A study of Sus scrofa with 30 samples.

How the data were processed

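Gene expression was measured in pig cerebral cortex on 30 Affymetrix porcine arrays, 3 biological replicates in each of 10 groups per the labels. The deposited values are intensity on a linear scale, scaled per array by the authors with GCOS, whose version, signal algorithm and further steps are not given in the sources used here. In the file, the mean over probe sets after leaving out the lowest and highest 2% was 300.05 to 300.06 on every array. The file held 24123 probe sets, of which 124 control probe sets (AFFX) were left out of all tests, and 23999 remained. Gene symbols came from the platform's own table: 10110 probe sets had 1 symbol, 157 had several and 13732 had none. Of the 10140 entries of the table with 1 symbol, 9989 matched the reference gene table by gene ID, and 0 of these had another symbol there. Genomic positions were not used here.

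Values were analysed as log2(intensity + 16). Probe sets with a mean log2 value below the 30th percentile, an intensity of about 29.5, were left out, so that 16799 were tested. Groups were compared with limma 3.58.1 in R 4.3.3, by a single fit with a mean for each of the 10 groups (20 residual degrees of freedom), empirical Bayes moderation with an intensity trend, two-sided tests, and Benjamini-Hochberg adjustment within each contrast at 0.05. The contrasts were CA5, CA20 and CA30 against CA0, each saline group against CA0, each methylene blue group against the saline group of the same time and against CA0, the mean of the 3 methylene blue against saline differences, and an interaction test of whether that difference varied between times. CA0 served as the control of several contrasts, so an overlap between contrasts that share it is no evidence of a common response, and none is given for the saline or the methylene blue groups against CA0. Errors of log2 changes are standard errors from the fit, and errors of intensities are standard deviations between arrays. The arrays have no counts, so the precision of each value is limited by the 3 arrays per group.

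Before the data were examined, the groups, contrasts, alternatives, 13 gene lists and 12 lists of cell type markers were fixed. The gene lists were immediate early genes, heat shock and cytosolic chaperones, unfolded protein response, cytokines with adhesion and NF-kB genes, hypoxia and glycolysis, oxidative stress defence, nitric oxide and cGMP pathway, mitochondrially encoded transcripts, nuclear-encoded respiratory chain, apoptosis and p53 targets, angiogenesis with matrix and vascular tone, glutamate and GABA transmission, and ribosomal proteins. The marker lists covered neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, smooth muscle, red and white blood cells, choroid plexus, meninges and sex-linked genes. Each list was tested with camera at a preset correlation of 0.01 on 1 probe set per gene, where at least 5 members were measured, and again with an estimated correlation and with fry. Counts of members were also taken with p-values adjusted over the list alone.

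Genes were named by a rule fixed at the same time. It took, among probe sets with 1 symbol that passed and whose groups did not overlap (10% of probe sets do so by chance with 3 against 3), the 10 with the largest change up and the 10 down. For the mean over times the sign had to be the same at all 3 times. It added the 4 members of each list with the smallest p, whether or not they passed, and a fixed set: FOS, EGR1, ATF3, HSPA1A, HMOX1, IL6, PTGS2, VEGFA, NOS1, NOS2, NOS3, MBP, GFAP and CLDN5. HSP70.2 stands for HSPA1A on this array, IL6 lay below the filter and NOS1 was not on the array. Where fewer than 5 probe sets passed, the 5 named genes with the smallest p were reported as not passing. For genes with several probe sets, the list values use a single probe set and the named values the one with the largest change.

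Single measures per array (spike-in controls, 3'/5' ratio of control transcripts, size of the reperfusion response) were compared by two-sided exact permutation tests. For the response, arm labels were permuted within each time, which gives 8000 relabellings. A comparison of 3 arrays with 3 has 10 splits, so a single-gene permutation test could not go below 0.1. The pipeline was tested on simulated data, drawn as normal noise around each probe set's mean with its residual standard deviation, with known changes added to some probe sets.

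Alternatives were a pseudocount of 1 or 64, no filter or the 50th percentile, quantile normalization or median centring, a fit to the compared groups alone, no intensity trend, array weights, the replicate number as a block, adjustment over all contrasts together, and each array left out in turn, for the gene lists also all probe sets of each gene, and for the response size a stricter threshold, a minimum change and the median over probe sets. Chosen after seeing the data were the 3'/5' ratio as a covariate, a fit without 5 arrays that stood apart (SAL30 replicate 1 and the 4 arrays with a log2 3'/5' ratio above 2), the comparison of 180 with 30 min within each arm, other sets of probe sets for the response size, and leave-one-out for the gene lists. No paired analysis was used as the main test because arrays with the same replicate number are not known to share an animal or a batch.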

Results

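Transcript levels were measured in the cerebral cortex of pigs on an Affymetrix porcine expression array, with 30 arrays in 10 groups of 3 biological replicates. A control group with 0 min of cardiac arrest (CA0) stood beside groups with 5, 20 and 30 min of untreated arrest (CA5, CA20, CA30). In the other 6 groups, 12 min of arrest were followed by 8 min of cardiopulmonary resuscitation, and cortex was taken 30, 60 or 180 min after return of spontaneous circulation (ROSC). These animals received saline alone (SAL30, SAL60, SAL180) or saline with methylene blue, a redox dye that inhibits nitric oxide synthase and guanylate cyclase (MB30, MB60, MB180). Saline ran at 55 ml/kg/h, with 7.5 mg/kg/h of methylene blue in the MB groups. The infusion lasted from 1 min after the start of resuscitation to 50 min after ROSC. Cortex at 30 min was thus taken during the infusion, and cortex at 60 and 180 min after its end. Median intensity ran from 87.1 to 105 arbitrary units on the 21 arrays of the CA and SAL groups and from 97.6 to 108 on the 9 MB arrays. The number of arrays, 3 per group, limits the precision of every value. Of the 16799 probe sets tested, 7885 carried a single gene symbol, and those stood for 5797 genes.

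The first comparison asked which transcripts changed during 5 min of arrest without resuscitation. No probe set passed in CA5 against CA0 with limma, and the smallest adjusted p was 0.086. An unadjusted p under 0.05 was found for 317, fewer than the 840 expected in each comparison if no probe set changed. GGA2, an adaptor of vesicle traffic, had the smallest p among named genes, with a log2 difference of 1.48 ± 0.30 (SE, n = 3 per group, adjusted p = 0.364) at intensities of 40.0 ± 5.48 (SD) against 4.02 ± 2.26. IL1B, the cytokine interleukin 1 beta, stood at 171 ± 56.0 (SD) in CA5 and 82.6 ± 5.97 in CA0, a log2 difference of 0.87 ± 0.23 that did not pass (adjusted p = 0.9999) but was the only 1 of 15 cytokine, adhesion and NF-kB genes called when adjusted over the list alone. GPR4, a proton-sensing receptor, had a log2 difference of -0.92 ± 0.24 that did not pass either. Among the immediate early genes, which cells transcribe within minutes of a stimulus, 0 of 27 measured members passed over all genes and 0 when adjusted over the list alone. The largest log2 differences among those named were 0.84 ± 0.42 for ZFP36 and 0.81 ± 0.30 for ATF3. As a set the immediate early genes lay above the other genes (camera adjusted p = 0.0015), but with adjusted p = 0.522 with an estimated correlation the call was lost. The same held for endothelial markers, which lay lower (adjusted p = 0.0049, and adjusted p = 0.522 with an estimated correlation), microglia markers (0.0371, and adjusted p = 0.587 with an estimated correlation) and ribosomal proteins (0.00637, and adjusted p = 0.69 with an estimated correlation). These list calls were also lost without single arrays: immediate early genes without CA0 replicate 3 (0.0843) or CA5 replicate 1 (0.194), endothelial markers without CA0 replicate 3 (0.0843), microglia markers without CA0 replicate 3 (0.561) or CA5 replicate 3 (0.333). Ribosomal proteins lost theirs without CA0 replicates 2 (0.585) or 3 (0.797) or CA5 replicates 1 (0.341) or 3 (0.0586). The count was 1 without CA0 replicate 3, 2 with a pseudocount of 1 and 9 with Benjamini-Hochberg adjustment over all contrasts together.

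With longer untreated arrest, 2 probe sets were higher than in CA0 at 20 min and 2 at 30 min, and 0 were lower. They were the same pair, neither of which has a gene symbol, and are described because they passed, after their values were seen. Both contrasts used the same CA0 arrays. The first rose from 125 ± 8.72 (SD, n = 3) to 445 ± 148 at 20 min and 562 ± 166 at 30 min, with limma adjusted p = 0.00579 and 0.000228. The second rose by 2.50 ± 0.41 and 2.55 ± 0.41 on the log2 scale (SE, adjusted p = 0.0153 and 0.0113). Unadjusted p-values under 0.05 numbered 712 at 20 min and 682 at 30 min, also fewer than the 840 expected if no probe set changed. ABCG2, a transporter of the blood-brain barrier, stood at 295 ± 22.1 (SD) at 20 min against 499 ± 53.7 in CA0, a log2 difference of -0.73 ± 0.14 that did not pass (adjusted p = 0.196). GGA2 differed by 1.22 ± 0.30 at 30 min without passing (adjusted p = 0.985). At 20 min the count was 1 without CA0 replicate 1 or CA20 replicate 3 and 0 without CA0 replicate 2 or CA20 replicate 2. At 30 min it was 1 without CA0 replicate 1, CA0 replicate 2, CA30 replicate 1 or CA30 replicate 3, and a fit to the compared groups alone gave 0 at both times.

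Some gene lists shifted as sets in untreated arrest, in groups that also differed in a sign of RNA quality. At 20 min the respiratory chain genes of the nucleus, the complexes that make ATP, had a lower set mean (camera adjusted p = 0.00096, and adjusted p = 0.633 with an estimated correlation), as had heat shock genes (0.0177, and adjusted p = 0.633 with an estimated correlation). At 30 min ribosomal proteins lay lower (adjusted p = 2.8e-08), as did immediate early genes (0.0359), heat shock genes (0.0192), oxidative stress genes (0.0492), apoptosis genes (0.0413) and microglia markers (0.0413), and smooth muscle markers lay higher (0.0292). For each of these 7 lists the call at 30 min was lost, at adjusted p = 0.462 with an estimated correlation, and 0 of their members passed in limma, over all genes or adjusted over the list alone. The log2 3'/5' ratio of control transcripts was 1.66 to 1.92 on the CA0 arrays, 1.16, 2.21 and 2.71 on CA20 replicates 1, 2 and 3, and 1.07 to 1.45 on the CA30 arrays. RNA quality and the length of arrest were thus not separated in these shifts. At 20 min the call for respiratory chain genes was lost without CA0 replicate 1 (adjusted p = 0.0912) and that for heat shock genes without CA0 replicate 2 (0.861) or CA20 replicate 1 (0.225). At 30 min, leaving out CA30 replicate 1 ended the calls for immediate early genes (0.789), heat shock genes (0.15), oxidative stress genes (0.526), apoptosis genes (0.167), microglia markers (0.146) and smooth muscle markers (0.15). Immediate early genes were also lost without CA0 replicate 1 (0.398) or 2 (0.0605), and heat shock genes without CA0 replicate 2 (0.82). Smooth muscle markers were also lost without CA0 replicate 2 (0.191) or CA30 replicate 3 (0.102). Apoptosis genes were also lost without CA0 replicate 1 (0.0852), CA0 replicate 2 (0.129) or CA30 replicate 2 (0.0506). Microglia markers were also lost without CA0 replicate 3 (0.522) or CA30 replicate 2 (0.0972). Oxidative stress genes were also lost without CA0 replicate 2 (0.13) or 3 (0.191). Through the shared spread they were lost (0.0501 to 0.0583) without CA5 replicates 2 or 3, CA20 replicate 3, SAL30 replicate 2, SAL60 replicate 3, any SAL180 array, MB30 replicate 3 or MB180 replicates 2 or 3.

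After resuscitation under saline, genes of several kinds were higher at 30 min of ROSC than in CA0. HSPA6, an inducible chaperone of the HSP70 family, rose from 116 ± 30.4 (SD, n = 3) to 2803 ± 743 (log2 change 4.41 ± 0.20 SE, limma adjusted p = 3.5e-14). ATF3, a stress-induced transcription factor, rose from 32.5 ± 7.91 to 594 ± 124 (3.64 ± 0.30, adjusted p = 3.1e-08). CXCL2, a chemokine that attracts neutrophils, rose from 32.3 ± 28.1 to 407 ± 64.8 (3.27 ± 0.43, adjusted p = 7.9e-05). DUSP1, a phosphatase that switches off MAP kinases, rose from 641 ± 221 to 3395 ± 607 (2.42 ± 0.30, adjusted p = 2.6e-05), and ADAMTS1, a secreted protease of the extracellular matrix, rose by 2.43 ± 0.25 on the log2 scale. In all, 31 probe sets were higher and 2 lower at 30 min, 46 and 7 at 60 min, and 104 and 43 at 180 min. Unadjusted p-values under 0.05 numbered 1240, 1059 and 1466.

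Immediate early genes formed the group with the most called members under saline. Of the 27 measured, 6 rose at 30 min, 6 at 60 min and 7 at 180 min, and 15, 16 and 14 did so when adjusted over the list alone. At 60 min the 6 became 2, ATF3 and CYR61, without CA0 replicate 3, SAL60 replicate 1 or SAL60 replicate 3, and at 180 min the 7 became 4 without SAL180 replicate 2. CYR61, a matrix-associated signalling protein, rose by 2.88 ± 0.29, 2.41 ± 0.29 and 1.92 ± 0.29 on the log2 scale at the 3 times (n = 3 per group). PPP1R15A, which directs a phosphatase to the translation factor eIF2-alpha, rose by 1.60 ± 0.24 at 30 min, and IER5 by 1.19 ± 0.16 and GADD45B by 1.54 ± 0.26 at 180 min. FOS, a subunit of the transcription factor AP-1, rose from 1035 ± 552 (SD) to 4109 ± 495 at 30 min (log2 change 2.11 ± 0.41, adjusted p = 0.0146), and at 180 min its log2 difference of 1.53 ± 0.41 did not pass (adjusted p = 0.0797). The call for FOS at 30 min was lost without CA0 replicate 3 (adjusted p = 0.273), SAL30 replicate 1 (0.105) or SAL30 replicate 3 (0.0519). EGR1, another early transcription factor, differed by 0.63 ± 0.45 at 30 min and did not pass (adjusted p = 0.77). The set test placed the list above the other genes at all 3 times (camera adjusted p = 9.9e-21, 2.0e-24 and 4.0e-21), and the call held with an estimated correlation (adjusted p = 0.00032, 0.00011 and 0.00019).

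Of 20 measured heat shock and cytosolic chaperones, 3, 3 and 5 were called as higher at 30, 60 and 180 min, and 4, 5 and 8 when adjusted over the list alone. Whether the list differed between these times was not tested. BAG3, a partner of HSP70 in the removal of damaged proteins, rose by 1.97 ± 0.30, 2.30 ± 0.30 and 2.96 ± 0.30 on the log2 scale (n = 3 per group). DNAJB1, a co-chaperone of HSP70, rose by 2.33 ± 0.28, 2.37 ± 0.28 and 1.87 ± 0.28. HSPB8, a small heat shock protein, rose by 1.17 ± 0.15 at 180 min. HSP70.2, an inducible chaperone whose sequence is close to that of HSPA6, rose by 2.50 ± 0.35, 2.46 ± 0.35 and 2.57 ± 0.35 on its list probe set, from a CA0 level of 2195 ± 1973 (SD) that 1 high array widened. Signal from transcripts of the same family was not separated for either gene. The set test passed at each time (camera adjusted p = 4.8e-05, 3.0e-07 and 3.6e-13). With an estimated correlation the calls at 60 and 180 min held (adjusted p = 0.048 and 0.0039), and that at 30 min was lost (adjusted p = 0.15 with an estimated correlation).

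Of the genes of angiogenesis, matrix and vascular tone, 1, 1 and 4 of 17 measured members were called at 30, 60 and 180 min, and 1, 1 and 7 when adjusted over the list alone. The 4 at 180 min became 1, ADAMTS1, without CA0 replicate 2 and 2 without SAL180 replicate 3. ADAMTS1 rose from 137 ± 34.8 (SD, n = 3) to 1121 ± 201 at 180 min (log2 change 2.91 ± 0.25 SE, limma adjusted p = 1.0e-07). PLAT, the tissue plasminogen activator, rose by 0.83 ± 0.16 (adjusted p = 0.00646), a call lost without CA0 replicate 2 (0.0595) or SAL180 replicate 3 (0.0648). The list passed the set test at each time, and also with an estimated correlation (adjusted p = 0.0221, 0.00705 and 0.00019). DDIT3, a transcription factor of the unfolded protein response, rose by 1.07 ± 0.15 at 180 min and was the only 1 of 18 measured members of its list to pass, over all genes or adjusted over the list alone. That list passed the set test at 180 min (camera adjusted p = 6.4e-06, and 0.0284 with an estimated correlation).

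Further genes called at 180 min belonged to other lists or to none. GADD45A, a growth arrest gene among the apoptosis and p53 targets, rose by 1.35 ± 0.19 on the log2 scale at 30 min and 1.90 ± 0.19 at 180 min (n = 3 per group), and 2 of 7 measured members of its list passed at 180 min, 2 also when adjusted over the list alone. The other, CDKN1A, lost its call without CA0 replicate 1 (adjusted p = 0.163), CA0 replicate 3 (0.172) or SAL180 replicates 1 (0.0867), 2 (0.115) or 3 (0.143), which left 1. That list lay higher at 180 min (camera adjusted p = 0.00428, and adjusted p = 0.0943 with an estimated correlation). SLC2A3, the glucose transporter GLUT3, rose by 0.93 ± 0.15, 1.08 ± 0.15 and 1.01 ± 0.15. It was among 2 of 23 measured hypoxia and glycolysis genes called at 180 min, 2 also when adjusted over the list alone. The other, ADM, lost its call without CA0 replicate 2 (adjusted p = 0.117), CA0 replicate 3 (0.138), SAL180 replicate 1 (0.119) or SAL180 replicate 2 (0.174), which left 1. That list had camera adjusted p = 0.00864 and adjusted p = 0.0518 with an estimated correlation, and its camera call was lost without SAL180 replicate 2 (0.0701). HMOX1, the heme oxygenase that breaks down heme, rose by 1.36 ± 0.30 at 180 min (adjusted p = 0.0204), the only 1 of 22 oxidative stress genes called, and its call was lost without CA0 replicate 1 (adjusted p = 0.18), SAL180 replicate 2 (0.124) or SAL180 replicate 3 (0.126). CEBPD, a transcription factor of acute inflammation, rose from 157 ± 61.3 (SD) to 685 ± 38.3 at 180 min, and RRAD, a Ras-related GTPase, from 31.9 ± 14.1 to 275 ± 81.1. FUCA2, a fucosidase, rose by 2.63 ± 0.24. DYNC1I2, a chain of the dynein motor, fell from 232 ± 47.0 to 40.8 ± 5.70 on 1 probe set (log2 change -2.11 ± 0.24, adjusted p = 9.3e-06), whereas its other probe set differed by -0.10. FBXW7, a subunit of a ubiquitin ligase, fell by 2.09 ± 0.25 on the log2 scale on 1 of its probe sets, with no call on the others. PABPN1, a nuclear poly(A)-binding protein, fell by 0.90 ± 0.12 on 1 probe set, and TTC14, a tetratricopeptide repeat protein, fell by 0.65 ± 0.12.

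**Figure D1:**
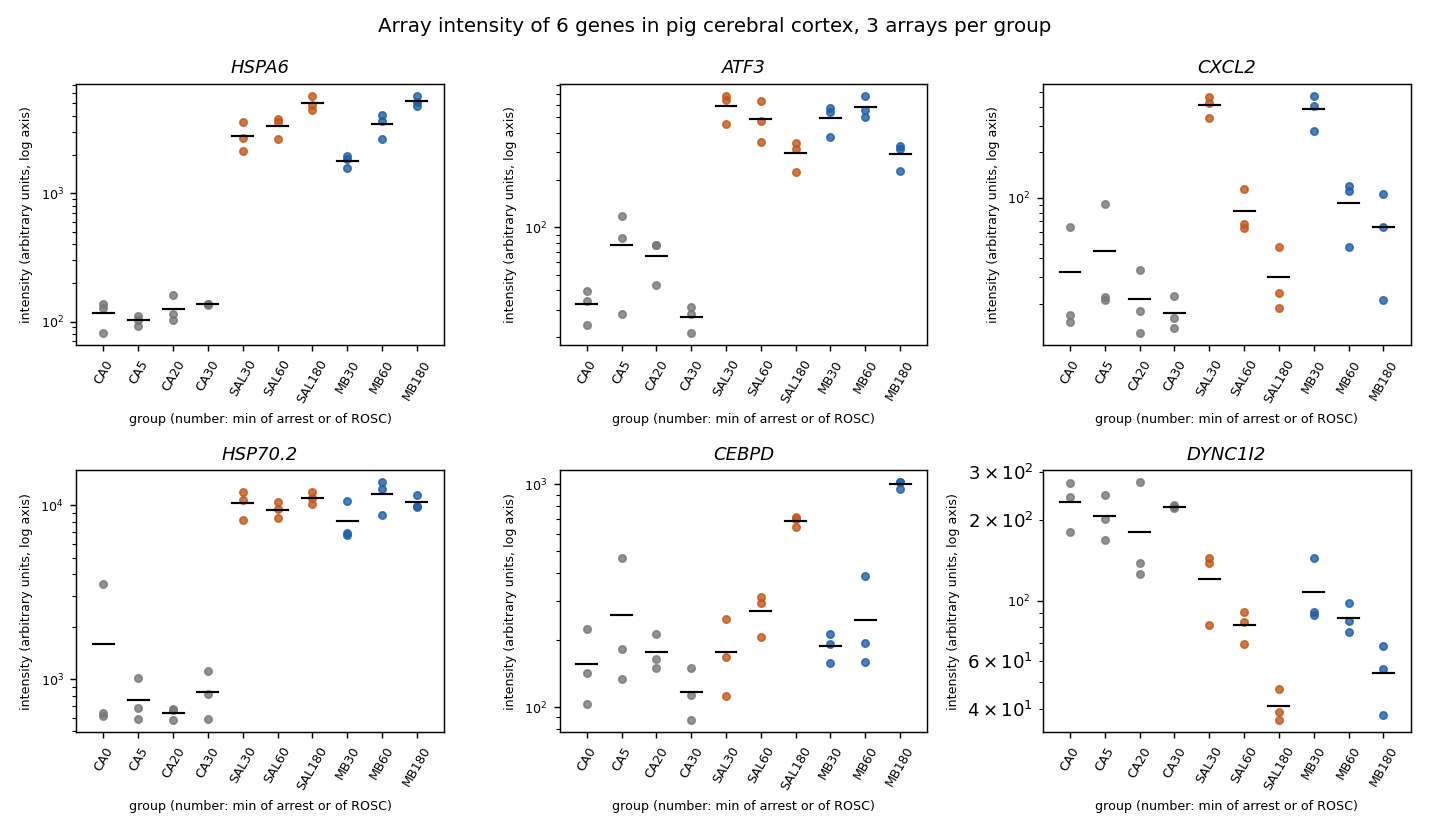
Array intensity (arbitrary units, log axis) of 6 genes in each of the 10 groups, with 1 point per array and a horizontal bar at the group mean of 3 arrays. HSPA6 stood at 116 in CA0, 2803 in SAL30 and 5007 in SAL180, and CEBPD at 157, 177 and 685, while DYNC1I2 fell from 232 to 40.8 in SAL180 on the probe set drawn.

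Several groups gave few or no called members under saline. Among cytokine, adhesion and NF-kB genes, CXCL2 was the only 1 of 15 to pass at 30 min, 0 passed in limma at 60 and 180 min (0 and 1 when adjusted over the list alone), and CXCL2 stood at 29.9 ± 15.4 (SD, n = 3) at 180 min. The set test of that list gave adjusted p = 0.0209 at 60 min and 0.0313 at 180 min, and adjusted p = 0.363 and 0.264 with an estimated correlation. Respiratory chain genes of the nucleus had camera adjusted p = 0.013 at 60 min and adjusted p = 0.627 with an estimated correlation, and ribosomal proteins 0.0165 and adjusted p = 0.782 with an estimated correlation. The cytokine call was lost without CA0 replicate 2 (0.46) or SAL60 replicate 2 (0.117) at 60 min and without CA0 replicate 2 (0.445) or SAL180 replicate 3 (0.133) at 180 min. The respiratory chain call was lost without CA0 replicate 1 (0.209) or SAL60 replicate 1 (0.73), and the ribosomal call without CA0 replicates 2 (0.455) or 3 (0.826) or SAL60 replicates 1 (0.23) or 3 (0.828). Of 14 genes of the nitric oxide and cGMP pathway, 0 passed in limma, over all genes or adjusted over the list alone. NOS2, the inducible nitric oxide synthase, differed by 0.86 ± 0.30 on the log2 scale at 180 min (adjusted p = 0.261). PTGS2, an inducible cyclooxygenase, differed by -0.11 ± 0.30 and CLDN5, a tight junction protein of brain endothelium, by 0.67 ± 0.24, and neither passed. VEGFA, a vascular growth factor, differed by -0.20 ± 0.16 without passing on its list probe set but was higher on another (0.85 ± 0.18, adjusted p = 0.0124), so its probe sets disagreed. Neuron, astrocyte, oligodendrocyte, microglia, endothelial, smooth muscle and meningeal markers had 0 members called in limma at the 3 times (when adjusted over the list alone, 1 endothelial marker higher and 1 microglia marker higher and 1 lower at 180 min), among them GFAP at 0.05 ± 0.23 and MBP at -0.02 ± 0.22 at 180 min.

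The counts under saline changed when single arrays were left out, which also lowers a group from 3 arrays to 2. At 60 min the count of 53 became 23 without CA0 replicate 3, 23 without SAL60 replicate 1 and 30 without SAL60 replicate 3, and at 180 min the count of 147 became 91 without CA0 replicate 2 and 96 without CA0 replicate 3. A fit to the compared groups alone gave 12, 19 and 55.

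Methylene blue was compared with saline at each time after ROSC, the question being what the drug adds to the reperfused cortex. PSMD4, a ubiquitin receptor of the proteasome, was higher under methylene blue at all 3 times, at 1198 ± 112 (SD, n = 3) against 385 ± 73.7 at 30 min, 1233 ± 125 against 313 ± 82.9 at 60 min and 1119 ± 85.8 against 332 ± 22.8 at 180 min. PIP5K1A, a lipid kinase that makes phosphatidylinositol bisphosphate, was higher by 2.08 ± 0.24, 1.96 ± 0.24 and 1.59 ± 0.24 on the log2 scale (SE, limma adjusted p = 2.3e-05, 3.5e-05 and 0.000754), on 1 probe set of 2. NDRG2, a gene expressed in astrocytes, stood at 3459 ± 469 against 953 ± 126 at 60 min, and PFDN6, a subunit of the chaperone prefoldin, at 559 ± 36.4 against 199 ± 26.6. POLR2B, a core subunit of RNA polymerase II, was lower at 30 and 180 min (-1.18 ± 0.22 and -1.24 ± 0.22, adjusted p = 0.00461 and 0.00484) on 1 probe set, and its other probe sets had no call at these times, although 1 of them was higher in the mean over times.

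At 30 min 403 probe sets were higher and 284 lower under methylene blue, at 60 min 122 and 134, and at 180 min 215 and 104, with 3572, 2910 and 3121 at an unadjusted p under 0.05. COG8, part of a Golgi tethering complex, was higher at 30 min on 1 probe set of 2 (1.87 ± 0.32, n = 3 per group, limma adjusted p = 0.00219), and FAM131C was lower (-2.09 ± 0.37, adjusted p = 0.00327). SLC37A4, a glucose 6-phosphate transporter, was higher by 1.79 ± 0.24 at 30 min and 1.59 ± 0.24 at 180 min. Ribosomal proteins lay lower as a set at 30 min (camera adjusted p = 0.00055, and adjusted p = 0.704 with an estimated correlation) and at 180 min (0.00057, and adjusted p = 0.948 with an estimated correlation), with 0 of 55 measured members called in limma at either time on the probe sets of the list. Other probe sets of these genes disagreed in direction. RPS28 was higher on 1 of them at 30 min (1.06, adjusted p = 0.00178), and RPL38 was lower on 1 at 180 min (-2.14 ± 0.56, adjusted p = 0.0456), a call lost without any 1 of the 6 arrays compared (adjusted p = 0.0511 to 0.221). Genes of the unfolded protein response lay lower at 180 min (0.0189, and adjusted p = 0.948 with an estimated correlation), with 0 of 18 called in limma on the probe sets of the list, over all genes or adjusted over the list alone. The ribosomal calls were lost without MB30 replicate 1 (0.175) and MB180 replicate 1 (0.23), and that of the unfolded protein response without SAL180 replicate 2 (0.0602) or MB180 replicate 1 (0.0701). With median centring of the arrays the split became 270 higher and 530 lower at 30 min, 103 and 176 at 60 min, and 170 and 502 at 180 min, where that scaling put the median of all probe sets at -0.11. With quantile normalization it was 381 and 414 at 30 min and 143 and 119 at 180 min.

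These counts changed when single arrays were left out. That also lowers a group from 3 arrays to 2, and the 2 reasons for a loss of calls were not separated. At 30 min the 687 became 246 without SAL30 replicate 1, 424 without SAL30 replicate 2, 1117 without SAL30 replicate 3, and 336, 286 and 292 without MB30 replicates 1, 2 and 3. At 60 min the 256 became 103 without SAL60 replicate 1, 27 without SAL60 replicate 2, 54 without MB60 replicate 2 and 111 without MB60 replicate 3. At 180 min the 319 became 99 without SAL180 replicate 1, 23 without SAL180 replicate 3, 611 without MB180 replicate 1, 40 without MB180 replicate 2 and 78 without MB180 replicate 3. PSMD4 and NDRG2 were called at 60 min in each of these fits for 60 min.

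Averaged over the 3 times, 2313 probe sets were higher and 1918 lower under methylene blue. NDRG2 stood at 3089 ± 402 (SD, n = 9) against 1067 ± 264 under saline (log2 change 1.54 ± 0.10 SE, limma adjusted p = 4.3e-11), and PSMD4 at 1183 ± 107 against 343 ± 65.2 (1.76 ± 0.12, adjusted p = 1.6e-10), with no overlap between the 9 arrays of each arm. ARID1B, a subunit of a chromatin remodelling complex, was lower, at 506 ± 147 against 944 ± 134. Of 55 ribosomal protein genes, 1 was higher and 13 were lower, the same when adjusted over the list alone, among them RPS9 (-0.42 ± 0.06) and RPS6 (-0.30 ± 0.06). As a set they lay lower (camera adjusted p = 0.00131), a call lost at adjusted p = 0.884 with an estimated correlation. Of 56 respiratory chain genes of the nucleus, 3 were higher and 9 lower, the same when adjusted over the list alone, with ATP5J, a subunit of ATP synthase, at -0.46 ± 0.07 and NDUFB9, a subunit of complex I, at -0.50 ± 0.09. The set test of that list did not pass (camera adjusted p = 0.543). Over all probe sets tested, 4231 of 16799 were called in this comparison, so the ribosomal and respiratory chain lists did not stand out by their share of calls. Of 18 genes of the unfolded protein response, 1 was higher and 5 were lower, 2 and 6 when adjusted over the list alone, with DDIT3 at 0.33 ± 0.08 and DNAJB9, a chaperone of the endoplasmic reticulum, at -0.39 ± 0.10 on the probe set of the list, although 2 other probe sets of DNAJB9 were higher (0.88 and 0.89, adjusted p = 0.000216 and 0.0012). The set test of that list did not pass (camera adjusted p = 0.053, and adjusted p = 0.884 with an estimated correlation), whereas with fry it lay lower (adjusted p = 0.0139).

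Methylene blue is known to act on the nitric oxide and cGMP pathway. Of 14 genes of that pathway, 3 were higher in the mean over times and 0 lower, the same when adjusted over the list alone. Over all probe sets tested, 4231 of 16799 were called in that comparison, so the list did not stand out by its share of calls. NOS2 stood at 61.2 ± 13.0 (SD, n = 9) against 35.1 ± 14.9 under saline (log2 change 0.63 ± 0.17 SE, limma adjusted p = 0.00988), and its other probe set did not pass. The mean log2 value of NOS2 over all arrays, 5.65, lay just above the filter at 5.51. Low intensities were higher on the MB arrays as a whole, with 37.2 against 29.8 at the 30th percentile of probe sets. NOS3, the endothelial nitric oxide synthase, differed by 0.31 ± 0.12 and did not pass (adjusted p = 0.067). HMOX1 was higher by 0.56 ± 0.17 (adjusted p = 0.02), among 2 of 22 oxidative stress genes that were higher and 2 that were lower, and PRDX1, a peroxiredoxin, was lower (-0.54 ± 0.11). IL1B was higher by 0.46 ± 0.13 and ICAM1, an adhesion molecule, was lower (-0.42 ± 0.15, adjusted p = 0.0418). They were the 1 higher and 1 lower of 15 cytokine, adhesion and NF-kB genes (1 and 0 when adjusted over the list alone), whose set test did not pass (camera adjusted p = 0.772). The call for ICAM1 was lost (adjusted p = 0.0545 to 0.0979) without any 1 of SAL30 replicates 1 and 2, SAL60 replicates 1 and 2, SAL180 replicates 1 and 3, the 3 MB30 arrays, MB60 replicates 2 and 3 and MB180 replicate 1. Of the genes raised after resuscitation under saline, ATF3 at 0.01 ± 0.17, FOS at 0.13 ± 0.24 and HSP70.2 at 0.05 ± 0.20 did not pass in the drug comparison, whereas HMOX1, DDIT3 and HSPB8 were among those that did and were higher. ADAMTS1, named after its value was seen, was lower (-0.42 ± 0.15, adjusted p = 0.0356), a call lost (adjusted p = 0.0547 to 0.0761) without any 1 of SAL30 replicates 2 and 3, SAL60 replicates 1 and 3, SAL180 replicates 2 and 3, MB30 replicates 1 and 2, MB60 replicate 2 and MB180 replicates 1 and 2. HSPB8 was higher by 0.39 ± 0.09 and HSPD1 by 0.24 ± 0.06, the 2 called of 20 heat shock genes.

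Some markers of cell types differed between the arms in the mean over times, a comparison in which 4231 of the 16799 probe sets tested were called. OPALIN at -0.69 ± 0.16 (log2, SE, n = 9 per arm) and MAL at -0.79 ± 0.24 were lower among 9 oligodendrocyte markers, and TYROBP, a microglia marker, was lower (-0.52 ± 0.15). In each of the next 5 lists 2 members were called, and 1 of the 2 lost its call without certain single arrays. Of 10 neuron markers SYT1 was higher (0.31 ± 0.09), as was SYN1, which was lost without SAL30 replicate 1 (adjusted p = 0.0505). Of 9 astrocyte markers SLC1A3 was higher (0.43 ± 0.13) and GLUL lower, and GLUL was lost without MB30 replicate 1 (0.0507) or MB180 replicate 2 (0.0536). Of 13 endothelial markers ENG was higher (0.48 ± 0.14), as was CDH5, which was lost (adjusted p = 0.0526 to 0.0745) without any 1 of SAL60 replicate 2, SAL180 replicates 1 and 3, MB30 replicate 1, MB60 replicates 1 and 2 and MB180 replicates 2 and 3. Of 8 smooth muscle markers ACTG2 was higher (0.53 ± 0.13), as was MYL9, which was lost (adjusted p = 0.0567 to 0.0758) without any 1 of SAL30 replicate 3, SAL60 replicate 3, SAL180 replicate 2, MB30 replicates 1 and 2, MB60 replicates 2 and 3 and MB180 replicate 3. Of 5 meningeal fibroblast markers COL3A1 was higher (0.87 ± 0.22), as was DCN, which was lost (adjusted p = 0.0511 to 0.11) without any 1 of the arrays of these arms other than SAL60 replicate 1, SAL180 replicate 1, MB60 replicate 3 and MB180 replicate 2. GFAP at -0.23 ± 0.13, MBP at 0.09 ± 0.13 and CLDN5 at -0.21 ± 0.14 did not pass.

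The MB arrays also differed from the SAL arrays in their control probe sets, and with all 9 MB arrays below the SAL arrays in the poly-A spike-ins, batch and treatment cannot be told apart in any comparison of the arms. The mean log2 intensity of the 8 probe sets for poly-A spike-in RNA, which is added before labelling, was 6.72 ± 0.25 (SD) on the 9 MB arrays and 7.68 ± 0.17 on the 9 SAL arrays, with no overlap (two-sided exact permutation test, p = 4.1e-05, the smallest that 48620 regroupings can give). The hybridisation spike-ins, added after labelling, differed by -0.01 between the arms (exact p = 0.941). The mean log2 ratio of 3' to 5' signal of control transcripts, a measure of RNA integrity and labelling length, was 0.98 ± 0.19 and 1.58 ± 0.53 (exact p = 0.00119). The intensity at the 30th percentile of probe sets was 37.2 ± 2.89 and 29.8 ± 2.56 (exact p = 0.000123). With the 3'/5' ratio as a covariate, an alternative chosen after seeing the data, 1457 probe sets were called in the mean over times, 78 at 60 min and 18 at 180 min. Without the 5 arrays that stood apart, also chosen afterwards, the counts were 281, 44 and 46 at the 3 times and 2490 in the mean. With median centring the mean comparison had 1502 higher and 3350 lower, and with quantile normalization 1924 and 2402.

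**Figure D2:**
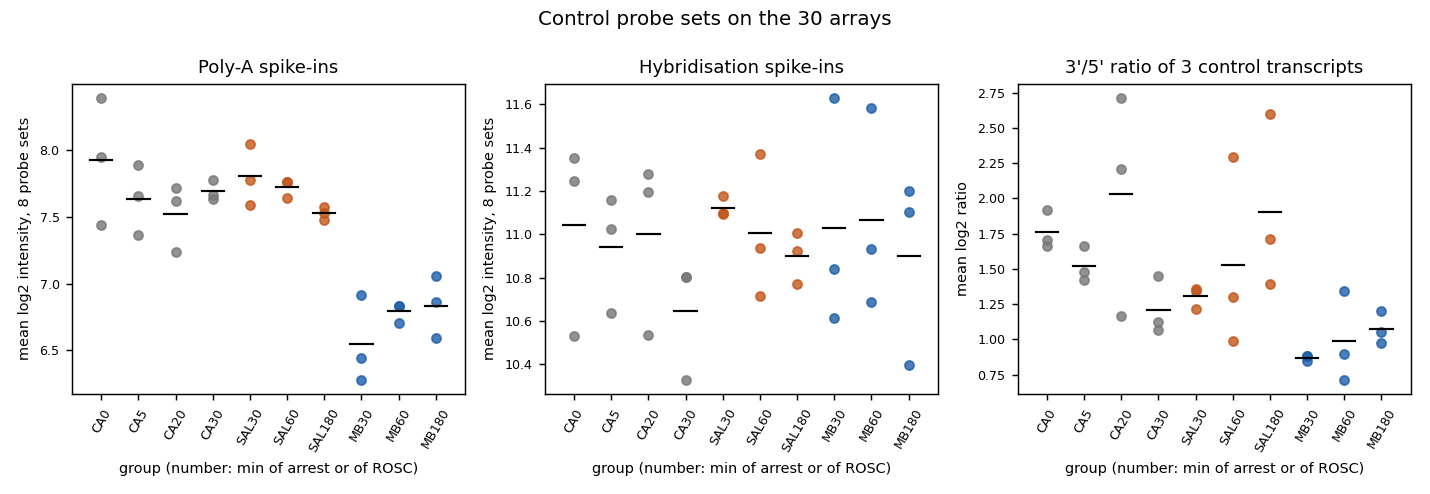
Control probe sets on the 30 arrays by group, with 1 point per array and a bar at the mean of 3 arrays, for poly-A spike-ins (mean log2 intensity), hybridisation spike-ins (mean log2 intensity) and the mean log2 3'/5' ratio. The 9 MB arrays lay between 6.28 and 7.05 for the poly-A spike-ins, below the 21 other arrays at 7.24 to 8.39.

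Across probe sets, the differences between arms at the 3 times were correlated. The log2 differences correlated at r = 0.63 between 30 and 60 min, 0.58 between 30 and 180 min and 0.61 between 60 and 180 min, across probe sets, which are not independent replicates, and no array was shared between times. PSMD4 and PIP5K1A were among 68 probe sets called at all 3 times, 68 of them with the same sign, while 994 were called at any time. Whether the drug's effect differed between times was tested as an interaction, and 0 probe sets passed in limma, with a smallest adjusted p of 0.9999. An unadjusted p under 0.05 was found for 483, fewer than the 840 expected if no probe set differed. With 3 arrays per group, the lack of calls does not show that the differences were equal. GPR4 and DIEXF stood first among genes with a symbol and were named after their values were seen. Benjamini-Hochberg adjustment over all contrasts together gave 12.

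The size of the reperfusion response was compared between arms as the mean log2 change from CA0, signed by direction, over the probe sets called in the mean of both arms at each time. The response was 1.31 under methylene blue and 0.75 under saline at 30 min (324 probe sets), 1.18 and 0.65 at 60 min (550) and 1.03 and 0.77 at 180 min (538). The pooled difference was 0.45 (two-sided exact permutation of arm labels within times, p = 0.00025, the smallest that 8000 relabellings can give). A probe set that differs from CA0 on the MB arrays alone can enter that set, signed so that the MB response looks larger. Under saline alone 33, 53 and 147 probe sets were called. The 0.45 thus cannot tell a larger response from the difference between the arms, in which batch and treatment cannot be told apart. For this reason 2 other sets were tried after seeing the data. Over probe sets called under saline, HSPA6 and ATF3 among them, the pooled difference was -0.07 (exact permutation p = 0.154). Over probe sets called under saline at the other 2 times, so that the arrays compared had no part in the choice, it was 0.06 (exact permutation p = 0.275).

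Against CA0, the methylene blue groups had 1273 higher and 771 lower probe sets at 30 min, 1184 and 922 at 60 min, and 957 and 623 at 180 min. All MB arrays also lay below the CA0 arrays in the poly-A spike-ins, which on CA0 had a mean log2 intensity of 7.44 to 8.39. Batch and treatment thus cannot be told apart in these counts either. HSPA6 stood at 1784 ± 194 (SD, n = 3), 3450 ± 725 and 5227 ± 485 at the 3 times, against 116 ± 30.4 in CA0. ATF3 stood at 496 ± 106, 583 ± 96.7 and 292 ± 54.7 against 32.5 ± 7.91, and CXCL2 at 384 ± 101, 92.6 ± 39.4 and 63.9 ± 42.4 against 32.3 ± 28.1. With median centring the splits were 750 higher and 2134 lower, 872 and 1955, and 559 and 1699, and that scaling put the median of all probe sets at -0.15, -0.13 and -0.13. With quantile normalization they were 831 and 965 at 30 min and 634 and 742 at 180 min. At 30 min the 2044 became 1208, 1267 and 1204 without CA0 replicates 1, 2 and 3, 1063 without MB30 replicate 2 and 1042 without MB30 replicate 3. At 60 min the 2106 became 1324, 1393 and 1318 without CA0 replicates 1, 2 and 3 and 901 without MB60 replicate 2. At 180 min the 1580 became 991, 867 and 786 without CA0 replicates 1, 2 and 3, 666 without MB180 replicate 2 and 822 without MB180 replicate 3. With the 3'/5' ratio as a covariate the counts were 442, 493 and 712.

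Lists with fewer than 5 measured members had no set test. Of the red blood cell markers 4 were measured, of the oligodendrocyte precursor markers 4, of glutamate and GABA genes 2, of choroid plexus markers 2, of white blood cell markers 1, of sex-linked genes 1 and of mitochondrially encoded transcripts 0. OLIG2, a transcription factor of the oligodendrocyte lineage, was lower under methylene blue in the mean over times (-0.77 ± 0.17 SE, n = 9 per arm, limma adjusted p = 0.00207) on 1 probe set, with 0.20 and no call on the other, and was the only member of these lists called in a comparison of untreated arrest with CA0, of saline with CA0 or of the arms. GAD1, which makes GABA, differed by -0.06 ± 0.18 between SAL180 and CA0, HBB, a haemoglobin chain, by -0.15 ± 0.18, AQP1, a water channel, by 0.88 ± 0.87 and LCP1, an actin-binding protein of leukocytes, by 0.69 ± 0.32, and none of these 4 passed. Astrocyte, endothelial, microglia, neuron, oligodendrocyte, meningeal and smooth muscle markers did not pass the camera test in a comparison under saline or of the arms. With fry, which does not compare a list with other genes, meningeal fibroblast markers lay higher under methylene blue at 30 min (adjusted p = 0.0228) and in the mean over times (0.00546), as did genes of angiogenesis in the mean (0.0274) and apoptosis genes in SAL30 against CA0 (0.0353).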

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

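The fit with the 3'/5' ratio as a covariate, the fit without 5 arrays that stood apart, the comparisons of 180 with 30 min within an arm, the 2 other sets for the response size and leave-one-out for the gene lists were chosen after seeing the data; the other alternatives were fixed beforehand. Leaving out the intensity trend, a pseudocount of 64, no filter and the replicate block moved no count by over 1.5 times. The numbers were not taken to pair the arrays, since deviations of same-numbered arrays correlated at -0.0036 on average, against 0.0019 for others, although all 3 correlations were over 0.1 in 2 of 45 pairs of groups, with 1 of the 12 compared, CA30 with CA0, among them. A pseudocount of 1 gave 2 calls for CA5, the 50th percentile filter 1321 for MB30 against CA0, quantile normalization 76 for MB180 against MB30, and median centring 672 for MB180 against SAL180. Array weights gave 1 for CA20, 94 and 362 for SAL60 and SAL180, 1258 for MB180 against SAL180 and 282 for SAL180 against SAL30. Adjustment over all contrasts together gave 9, 22 and 14 for CA5, CA20 and CA30, 83, 104 and 242 for the saline groups, 2258 for the mean of the methylene blue differences, 1151, 1261 and 985 for methylene blue against CA0, and 12 for the interaction. A fit to the compared groups alone, which has 4 residual degrees of freedom for 2 groups against 20, gave 0 for CA20, 0 for CA30, 12, 19 and 55 for saline, 27, 63 and 15 for methylene blue against saline, 1278 and 641 for MB60 and MB180 against CA0, and 4 and 6 for 180 against 30 min under saline and methylene blue. The 3'/5' covariate gave 78, 18 and 1457 for methylene blue against saline at 60 min, at 180 min and in the mean, 442, 493 and 712 against CA0, and 64 for SAL180 against SAL30. Without the 5 arrays, which leaves 1 array in CA20 and 2 in each saline group, CA20 had 1 (its spread comes only from the other groups, so this says little), CA30 had 1, methylene blue against saline had 281, 44, 46 and 2490, and SAL180 against SAL30 had 28. Gene list calls fell from 33 to 9 with an estimated correlation and 17 with fry. The response size of 0.45 became -0.0652 (exact p = 0.154) and 0.0557 (exact p = 0.275) with sets chosen under saline. It was 0.40 to 0.56 in the settings fixed beforehand other than leave-one-out (exact p = 0.00025, the smallest possible, and 0.0039 by sign flips). Those settings all took the set from the mean of both arms, so they do not test that choice. Except where the construction shows it, the cause was not tested.

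With each array left out in turn, counts ranged from 0 to 1 for CA5, 0 to 2 for CA20 and 1 to 2 for CA30, 24 to 41, 23 to 47 and 91 to 133 for SAL30, SAL60 and SAL180. For methylene blue against saline they ranged from 246 (without SAL30 replicate 1) to 1117 (without SAL30 replicate 3), from 27 (without SAL60 replicate 2) to 221 and from 23 (without SAL180 replicate 3) to 611 (without MB180 replicate 1), and in the mean from 3326 to 4547. Against CA0 they ranged from 1042 to 1479, 901 to 1786 and 666 to 1605. SAL180 against SAL30 had 43 to 107, MB180 against MB30 20 to 60, the interaction 0 to 0, the gene lists 29 to 42, and the response size 0.39 to 0.50. There were 211 calls of named genes, counted per contrast, so a gene called in several contrasts counts more than once. Of these calls, 94 held in every setting fixed beforehand other than leave-one-out, and 0 changed sign. MBP, which was not called (0.09, adjusted p = 0.648), became -0.16 (adjusted p = 0.0105) in the mean of the methylene blue differences with quantile normalization. Signal near background limits genes of low intensity, where the pseudocount of 16 shrinks changes. In simulated data, 66% of probe sets changed by 1 and 18% of those changed by 0.5 on the log2 scale were called in SAL180 against CA0.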

Other observations

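The comparisons within an arm and every test in this part were chosen after the result concerned had been seen, apart from the count of hypothalamus markers, whose bounds were written before its values. The bounds for the splits of the samples were written afterwards.

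Within each arm, the cortex at 180 min differed from that at 30 min after ROSC in genes of several kinds. CXCL2 was lower at 180 min under saline (-3.24 ± 0.43 SE on the log2 scale, n = 3 per group, limma adjusted p = 0.000226) and under methylene blue (-2.45 ± 0.43, adjusted p = 0.00595). DUSP1 was also lower in both (-1.58 ± 0.30 and -1.37 ± 0.30), and CEBPD was higher (1.92 ± 0.34 and 2.32 ± 0.34), as were HSPB8 (1.19 ± 0.15 and 1.14 ± 0.15), HSPA6 (0.86 ± 0.20 and 1.54 ± 0.20) and SIX4, a homeobox transcription factor (1.54 ± 0.24 and 1.44 ± 0.24). In all, 70 probe sets were higher and 40 lower under saline, and 31 and 17 under methylene blue, with 31 called in both with the same sign against 0.17 expected if the arms were independent. Median centring gave 100 higher and 33 lower under saline. Under saline the 110 became 48 without SAL180 replicate 1 and 43 without SAL180 replicate 3. Under methylene blue the 48 became 26, 20 and 28 without MB30 replicates 1, 2 and 3, 29 without MB180 replicate 1 and 22 without MB180 replicate 3. No array is shared between the arms, and a difference in processing between arms cancels within each, so these changes may reflect a time course common to both: of the 110 probe sets, 97.3% had the same sign under methylene blue. Handling that varied with time in both arms stays open.

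The methylene blue arrays differed from the saline arrays at all 3 times. A separate labelling of the methylene blue arrays is a candidate explanation, since the spike-in RNA added before labelling differed by -0.96 (log2) between the arms while the hybridisation spike-ins differed by -0.01, although a larger share of messenger RNA in the total RNA could also lower the former. The 3'/5' ratio as the whole cause is argued against, since 1457 probe sets were called with it as a covariate, 1324 of them among the 4231, with a median of 81.0% of the change kept. An action of methylene blue on the cortex cannot be told apart from these, because each methylene blue array lies below the saline arrays in the poly-A spike-ins, and a correlation of 0.58 between the differences at 30 and 180 min would follow from either.

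The library SAL30 replicate 1 stood apart from the other arrays. Tissue from the hypothalamus in it may account for part of this: of 57 listed markers 13 were measured, and 46.2% of these, 6 genes, were highest of 30 arrays in this library. For an array that does not stand apart 3.33% would be so by chance. The share of all probe sets that were highest in this library was not computed. The 46.2% therefore cannot tell hypothalamus tissue from a library that is extreme for many genes. PEG10 stood at 4482 against at most 2610 elsewhere, NNAT at 4005 against 1588 and POMC at 125 against 52.6. NPY went the other way: at 88.7 it was the lowest of 30, far below the mean of 1041 on the other arrays. SST, PNOC, NR5A1 and GHSR also lay below the mean of the others (log2 differences -0.40, -0.33, -0.21 and -0.11). CARTPT and NDN lay slightly above it (0.18 and 0.30). The median difference over the 13 was 0.30. The 13 had means of 29.1 to 2266 on the other arrays, with POMC the lowest and near background. Of 8 measured cortex markers, 4 were lowest of 30 in this library and their median difference was -0.50, barely past the bound of -0.5 set beforehand. Another cortical area or layer was not tested.

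Stress genes such as HSPA6, ATF3 and BAG3 were higher after resuscitation. For 180 min, RNA integrity as the whole cause is argued against by 159 probe sets called in SAL180 against CA0 with the 3'/5' ratio as a covariate. The arrays that stood apart as the whole cause are argued against by 112 called without them. The log2 3'/5' ratio was 1.22 to 1.35 on the SAL30 arrays, below the 1.66 to 1.92 on CA0, and the fits given here cover 180 min only. The 10 named genes with the largest rise at 180 min stayed called in both fits, with HSPA6 at 5.32 and 5.36 and ATF3 at 2.70 and 2.55 on the log2 scale (limma adjusted p at most 0.00856). Untreated arrest of 5, 20 or 30 min showed no such levels, with HSPA6 at 102, 126 and 137 against 116 in CA0 and at least 2803 under saline, and ATF3 at 77.1, 66.2 and 26.9 against 32.5 and at least 295. What followed the arrest, namely resuscitation, reperfusion, the saline infusion and the time to sampling, came together in the saline groups, so the rise could come from any of these or from a late effect of the arrest, and the sex of the animals was not tested.

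Other splits of the same arrays were counted for each comparison. For groups of 3 against 3 the 10 splits are too few for a share under 0.05. The real split gave 0 calls for CA5 against a highest of 6 among the others, 2 against 1 for CA20, 2 against 0 for CA30, and 33 against 1, 53 against 0 and 147 against 0 for the saline groups. It gave 687 against 15, 256 against 0 and 319 against 0 for methylene blue against saline, 2044 against 0, 2106 against 1 and 1580 against 1 for methylene blue against CA0, and 110 against 1 and 48 against 3 for 180 against 30 min in the saline and methylene blue arms. For the mean of the methylene blue differences, 1 of 100 splits, the real one, gave as many as 4231. This argues against chance as the grouping's source but does not exclude it, since only 100 splits were drawn. The highest other gave 1405, in a split that exchanges the arms apart from 1 array of each and so restates their difference. For the interaction, 100 of 100 splits gave at least the real 0, with a highest of 30. No split can give fewer than 0, so this share cannot decide anything. For the 33 gene list calls, 53 of 100 splits gave as many, with a highest of 72, so chance is not excluded. For the 9 calls with an estimated correlation it was 1 of 100, the real one, with a highest other of 6. This argues against chance for the total of 9 but for no single call among them, since only totals were compared.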
